A study of Apocynum venetum with 18 samples.

How the data were processed

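Leaf RNA of Apocynum venetum was sequenced in 18 libraries, 3 at each of 6 sampling times. Groups and replicate numbers were taken from the sample titles and the labelled time points. Per the labels' protocols, plants were moved to a nutrient solution with 300 mmol/L NaCl and leaves were frozen in liquid nitrogen. The values were tables of the whole series, with 1 column per library, and 0 per-sample columns were left unused.

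The authors' deposited estimated counts, of which 89.6% were not whole numbers, were not scaled between libraries. Per the file headers and feature IDs, features were Trinity transcripts assembled without a genome; the counting tool, aligner, filters and versions are not given in the sources used here. The authors also deposited FPKM values for the same features and libraries. Count divided by FPKM gave each feature's length, within 0.1 nucleotides of a whole number for 99.98% of features and from 301 to 15981 nucleotides. Total counts were 17933939 to 24731213 per library. No genome or annotation of this plant was used.

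The deposited annotation columns were not used. They name 3458 features (6.46%). Lengths stated for KEGG alignments were taken to be in amino acids and converted to nucleotides, a unit that was not checked. Of 829 KEGG alignments that state a length, 269 (32.4%) were over 1.1 times as long as the feature they stand on, a tolerance chosen after the values were seen. The share was 34.1% on average over 1000 shuffles of lengths among annotated features with similar ID and isoform numbers (95% of shuffles from 32.3% to 36.1%). The 25 gene lists fixed for this tissue and treatment were therefore not tested, which departs from the plan, and the rule for features without names was followed. By that rule the text names the 2 features with the largest rise and the 2 with the largest fall in the comparison with most calls. Each had to be called, to have at least 10 CPM in every library of its higher group and to show no overlap between the 2 groups.

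Estimated counts were rounded to whole numbers first. Features were filtered with filterByExpr, which left 45222, and scaled by TMM. A single model of the 6 groups was fitted to all 18 libraries with edgeR 4.0.16 (R 4.3.3), and contrasts were tested with its quasi-likelihood F-test. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1; the test over any time used the adjusted p alone. The common dispersion was 0.24. The SE of a log2 change was its size over the square root of F. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2. A group without counts was set to a floor of 3 counts over its libraries, and this floor and the Poisson intervals cover counting error only. The rule for named features, the tests, the call thresholds and most alternatives were fixed before the data were examined. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.

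The fit was tested on simulated counts with the means and dispersions of these features, in which 200 of the features were changed at 48 h and 44017 passed the filter. For 48 h against 0 h it recovered 11.9% of features changed by 1.5 on the log2 scale, 19.4% of those changed by 2 and 47.0% of those changed by 3, with 1 false call and 0 in the wrong direction. Detection was thus incomplete where few features change. Unchanged groups were simulated in 5 runs to find what sharing the 0 h libraries gives by itself. Replicate pairs of each time differed far beyond sampling noise, with a chi-square per degree of freedom of 11.8 or more, so no library was counted as a repeat of another.

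Alternatives were DESeq2 1.42.0 size factors in the same fit, the DESeq2 test, no filter on low counts, a filter of 10 CPM in 3 libraries, other fold thresholds, the replicate number as a block, only the 6 libraries compared, each library left out in turn, and limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) for features with an FPKM of at least 1 in 3 libraries. The FPKM values were not scaled by TMM. Features of at least 1000 nucleotides, and leaving out the libraries labelled 0 h replicate 2 and 2 h replicate 2, were added after seeing the data.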

Results

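Leaf RNA of Apocynum venetum, a fibre and medicinal shrub of saline ground, was profiled by RNA sequencing over 48 h in a nutrient solution with 300 mmol/L NaCl. The 18 libraries fell into 6 groups of 3, sampled at 0 h and after 2 h, then at 6 h, at 12 h, at 24 h and lastly at 48 h, and the labels give every group, 0 h included, the salt solution. The design text describes wild seedlings and an unsalted control group, but no library carries an unsalted label. The labels do not settle whether plants sampled at 0 h had been in salt, and no later time has unsalted libraries beside it. Every comparison is therefore between sampling times, and time in salt is not separated from handling or, where the clock times differ, from hour of day. Nothing in the labels ties each library to its own plant, so the p-values measure the spread between these libraries. Expression was given for 53545 features, each an assembled transcript named by an ID and not a gene, with a median length of 759 nucleotides. Several features can belong to one gene, so counts of features are not counts of genes. The total estimated count ranged from 17933939 in the library labelled 0 h replicate 2 to 24731213 in 48 h replicate 3. Gene names were not used, for the reasons given with the processing, and features are described by level, length, direction and time.

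Leaf RNA at 12 h, at 24 h and at 48 h resembled the 0 h libraries less on average than leaf RNA at 2 h or 6 h. The first principal component of log2 CPM held 35.7% of the variance and separated the 24 h and 48 h libraries (scores of 101.8 or more) from the rest (24.6 or less), and the second held 14.6%. Mean Spearman correlation with the 0 h libraries, taken across features, was 0.884 at 2 h, 0.867 at 6 h, 0.836 at 12 h, 0.785 at 24 h and 0.770 at 48 h. Within a time the mean correlation was 0.904 to 0.930, above the mean correlation of each later time with 0 h; these differences were not tested. Of the 45222 features tested, 19514 (43.2%) differed somewhere in the course. The libraries labelled 0 h replicate 2 and 2 h replicate 2 lay between their groups: the former correlated at 0.886 with its own time and 0.919 with the other 2 h libraries, and the latter at 0.892 with its own time and 0.908 with the other 0 h libraries. The order of 2 h and 6 h rested on these libraries, since among the others single correlations with 0 h were 0.831 to 0.859 at 2 h and 0.833 to 0.879 at 6 h.

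**Figure D1:**
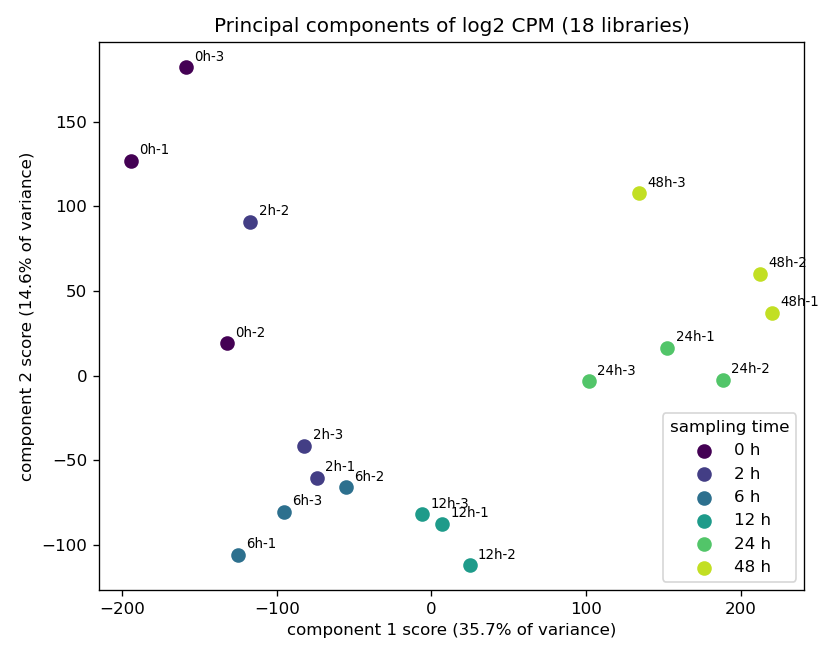
Scores of the 18 libraries on the first and second principal components of log2 CPM, with each point labelled by sampling time and replicate. The axes hold 35.7% and 14.6% of the variance; the 24 h and 48 h libraries lie at the right, and the libraries labelled 0 h replicate 2 and 2 h replicate 2 lie between the remaining 0 h and 2 h libraries.

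The comparison of 2 h with 0 h asked how far leaf RNA had changed soon after transfer to salt. At 2 h 227 features rose and 97 fell, 0.7% of those tested. The median log2 change was 2.79 among the rises, or 2.68 with the 33 features that had no counts at 0 h set to the bound of 3 counts over the group, and -2.90 among the falls. Of the rises, 193 were also called higher at 48 h, and of the falls 69 were also called lower there. The count depended on the test and on single libraries. The DESeq2 test called 2083 features, the replicate block 96, and a fit of only the 6 libraries compared called 1. Calls numbered 5 without 0 h replicate 1, 29 without 0 h replicate 3, 38 without 2 h replicate 1 and 14 without 2 h replicate 3, but 2834 without the library labelled 0 h replicate 2 and 1505 without that labelled 2 h replicate 2. With both of the latter left out, an alternative chosen after seeing the data, 3243 features rose and 2552 fell, so the size of the early change was not settled by these 6 libraries.

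Most features called at 6 h were higher than at 0 h. At this time 2112 features rose and 782 fell, so that 73.0% of calls were rises. The median log2 change was 2.22 among rises and -1.99 among falls. Of these, 1262 of the rises (59.8%) and 330 of the falls (42.2%) were called in the same direction at 48 h, while 115 of the rises and 51 of the falls were called in the opposite direction there. Calls numbered 374 with only the 6 libraries compared, 5318 with the DESeq2 test, 1604 at a log2 change of at least 2, 1659 without 0 h replicate 1, 1204 without 0 h replicate 3 and 1917 without 6 h replicate 3. Leaving out the libraries labelled 0 h replicate 2 and 2 h replicate 2 together gave 5358 calls at 6 h, of which 3371 were rises, and 5795 at 2 h, so that more features being called at 6 h than at 2 h did not hold without them.

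At 12 h more than 1 in 6 tested features had changed, with 4740 higher and 3023 lower than at 0 h (17.2%). The median log2 change was 2.29 among rises and -1.85 among falls. Most of these calls lasted, since 3309 of the rises and 2088 of the falls were called in the same direction at 48 h. With limma on log2(FPKM + 1), whose values were not scaled by TMM, 3879 features rose and 3952 fell. Without 0 h replicate 1 the count was 5167, and without 12 h replicate 2 it was 5086. Leaving out the libraries labelled 0 h replicate 2 and 2 h replicate 2 gave 10200.

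At 24 h features changed in both directions. Of 12302 calls, 27.2% of the features tested, 6692 were rises and 5610 were falls. The median log2 change was 2.46 among rises and -2.01 among falls. Of these, 5564 rises and 4391 falls were called in the same direction at 48 h, and 3 rises and 1 fall in the opposite one. At this time 9 features that had at most 3 counts over the 0 h group stood at 10 CPM or more in each library. The balance of directions depended on the processing and on which features were tested. With limma on log2(FPKM + 1), whose values were not scaled by TMM, 4993 features rose and 8521 fell. TMM factors were 1.11 to 1.16 at 0 h and 0.79 to 1.04 at 24 h. With TMM, 3064 rose and 3256 fell with at least 10 CPM in 3 libraries. Among features of at least 1000 nucleotides, chosen after seeing the data, 3807 rose and 3995 fell. No library left out alone moved the count by more than 1.5 times, and without the libraries labelled 0 h replicate 2 and 2 h replicate 2 it was 13966.

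The comparison of 48 h with 0 h had the most calls, 14485 or 32.0% of the features tested. Of these, 7388 were rises and 7097 were falls, but 4639 features rose and 10590 fell with limma on log2(FPKM + 1). The FPKM values were not scaled by TMM, whose factors were 1.11 to 1.16 at 0 h and 0.74 to 0.84 at 48 h. Leaving TMM out lowers 48 h values against 0 h. With TMM and at least 10 CPM in 3 libraries, which left 17495 features, 3365 rose and 4060 fell. The balance of directions thus also depended on which features were tested. In the main fit the median log2 change was 2.44 among rises, of which 706 had no counts at 0 h. It was -2.27 among falls, of which 403 had no counts at 48 h. With these features set to the bound the medians were 2.43 and -2.26. Among called features with at least 10 CPM in every library of the higher group, 3237 rises and 2642 falls had no overlap between the groups; chance gives 10% for a feature picked without regard to its values, which is no reference for features already called. Leaving out single libraries gave 11782 to 15152 calls, and leaving out the libraries labelled 0 h replicate 2 and 2 h replicate 2 together gave 15827.

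Among those features TRINITY_DN16846_c1_g1_i10_7, of 4966 nucleotides, rose the most. It had 1 count over the 3 libraries at 0 h and 482 CPM ± 136 (SD, n = 3) at 48 h, a ratio of 33700 with a 95% exact Poisson interval of 6050 to 1330000 for the single count. Its fitted log2 change was 7.72 (SE 1.16, adjusted p = 0.00042) at 12 h, 13.94 (SE 1.18, adjusted p = 5.2e-06) at 24 h and 14.56 (SE 1.19, adjusted p = 1.5e-06) at 48 h. These values depend on the default prior count of the fit, which is not the prior count of 2 used for log2 CPM. TRINITY_DN15842_c0_g1_i6_8, of 2124 nucleotides, also had 1 count at 0 h. It stood at 10.4 CPM ± 9.18 at 12 h, 45.1 ± 10.2 at 24 h and 198 ± 34.5 at 48 h, with a log2 change at 48 h of 13.27 (SE 1.80, adjusted p = 4.5e-05). Its ratio was 13800, with a 95% exact Poisson interval of 2480 to 545000 for the single count. Without 0 h replicate 2 its log2 change was 15.10. TRINITY_DN16367_c0_g1_i7_8, of 1710 nucleotides, fell the most. It stood at 97.8 CPM ± 26.9 at 0 h, 51.7 ± 10.1 at 12 h and 0.331 ± 0.574 at 24 h, and no count was found at 48 h, where it was at least 1880-fold lower by a floor of 3 counts over the group (adjusted p = 3.8e-06). TRINITY_DN12386_c0_g1_i2_8, of 1990 nucleotides, went from 257 CPM ± 241 at 0 h to 55.6 ± 58.9 at 6 h, 10.5 ± 3.28 at 12 h and 0.834 ± 1.00 at 48 h. Its log2 change was -4.62 (SE 1.07, adjusted p = 0.0066) at 12 h and -8.23 (SE 1.29, adjusted p = 0.00015) at 48 h, and its 0 h libraries held 1128 to 10592 counts. The change at 48 h was -7.18 without 0 h replicate 2 and -9.86 without 48 h replicate 3.

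Steps between neighbouring times compared each group with the one before it. From 2 h to 6 h 799 features rose and 270 fell. From 6 h to 12 h 30 rose and 79 fell, from 12 h to 24 h 886 rose and 1354 fell, and from 24 h to 48 h 65 rose and 132 fell. Falls outnumbered rises in each step after 6 h, but with only the 6 libraries compared 88 rose and 43 fell from 24 h to 48 h, and from 6 h to 12 h rises outnumbered falls without 6 h replicate 3, 12 h replicate 2 or 12 h replicate 3. The choice of test and single libraries moved each count. The DESeq2 test called 2796 features from 2 h to 6 h, 1230 from 6 h to 12 h, 4074 from 12 h to 24 h and 1071 from 24 h to 48 h. With only the 6 libraries compared 83 were called from 2 h to 6 h and 131 from 24 h to 48 h, and with the replicate block 599 and 89. From 2 h to 6 h the count was 344, 613 and 214 without 2 h replicates 1, 2 and 3, and 276 and 657 without 6 h replicates 1 and 3. From 6 h to 12 h it was 43, 68 and 2 without 6 h replicates 1, 2 and 3, and 10, 7 and 16 without those of 12 h. From 12 h to 24 h it was 1305, 1259 and 609 without 12 h replicates 1, 2 and 3, and 874 and 1189 without 24 h replicates 1 and 2. From 24 h to 48 h it was 17 without 24 h replicate 1, and 31 and 10 without 48 h replicates 1 and 2. The number of hours differs between steps, and the counts of 2 steps were not compared by a test.

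**Figure D2:**
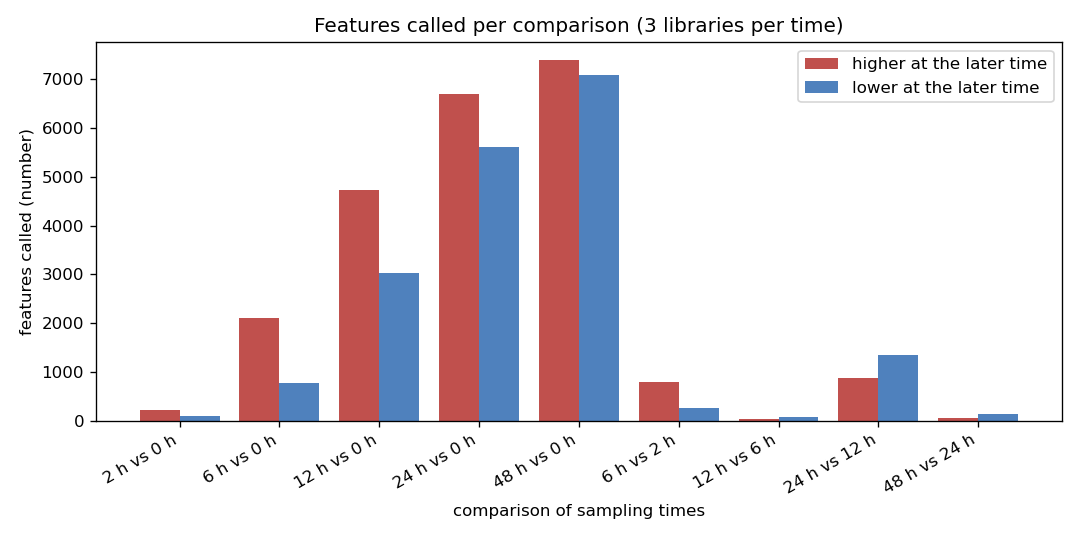
Number of features called per comparison of 2 sampling times, as bars for features higher and lower at the later time, with 3 libraries per time. Calls against 0 h went from 324 at 2 h to 14485 at 48 h, and among the steps the count was 2240 from 12 h to 24 h and 109 from 6 h to 12 h.

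Features called at one time were largely called at the next. Between 24 h and 48 h 9955 features were called in the same direction and 4 in opposite ones, where independent lists would share 1093 rises and 880 falls. Between 6 h and 12 h 1866 rises and 543 falls were shared, against 221 and 52.3 for independent lists. Between 6 h and 48 h 1592 calls were shared in direction and 166 were opposed. The 5 comparisons share the 0 h libraries, which by itself makes their log2 changes covary. Across features the covariance of log2 changes was 3.84 for 24 h and 48 h against a simulated 0.312, and 1.69 for 6 h and 48 h against 0.310. The correlation of log2 changes across features was 0.87 for 24 h and 48 h against a simulated 0.49, and 0.52 for 6 h and 48 h against 0.50. The simulated correlations hold for groups in which only noise varies. Real changes widen the spread by which a correlation is divided, so these values do not show how much of the correlation comes from the shared libraries. The 3 libraries at 0 h are too few to give each comparison 2 of its own, so part of each excess in covariance may rest on them. Shared calls between 6 h and 12 h numbered 1358, 3614 and 1074 without 0 h replicates 1, 2 and 3, and those between 6 h and 48 h numbered 829, 2583 and 713.

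Sorted by the time of their largest change, more features had their largest change at 48 h than at any other single time. Of 18764 features called against 0 h in at least 1 of the 5 comparisons, 4380 had their largest change as a rise at 48 h (23.3%) and 5246 as a fall at 48 h (28.0%). At 24 h 2902 rises and 2293 falls had their largest change, at 12 h 1569 and 1047, at 6 h 622 and 437, and at 2 h 130 and 138. Features with the largest rise at 6 h were transient in the median: 2.17 on the log2 scale at 6 h, 1.66 at 12 h, 0.56 at 24 h and 0.32 at 48 h. Those with the largest fall at 6 h were at -2.71, -1.67, -0.74 and -0.36. By contrast, features with the largest rise at 48 h stood at 0.47 at 6 h, 1.04 at 12 h, 1.69 at 24 h and 2.33 at 48 h. The times were picked from the same values, which lifts the median at the chosen time. Without the libraries labelled 0 h replicate 2 and 2 h replicate 2, 1019 rises and 1836 falls had their largest change at 2 h, and 4555 rises and 4885 falls at 48 h.

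**Figure D3:**
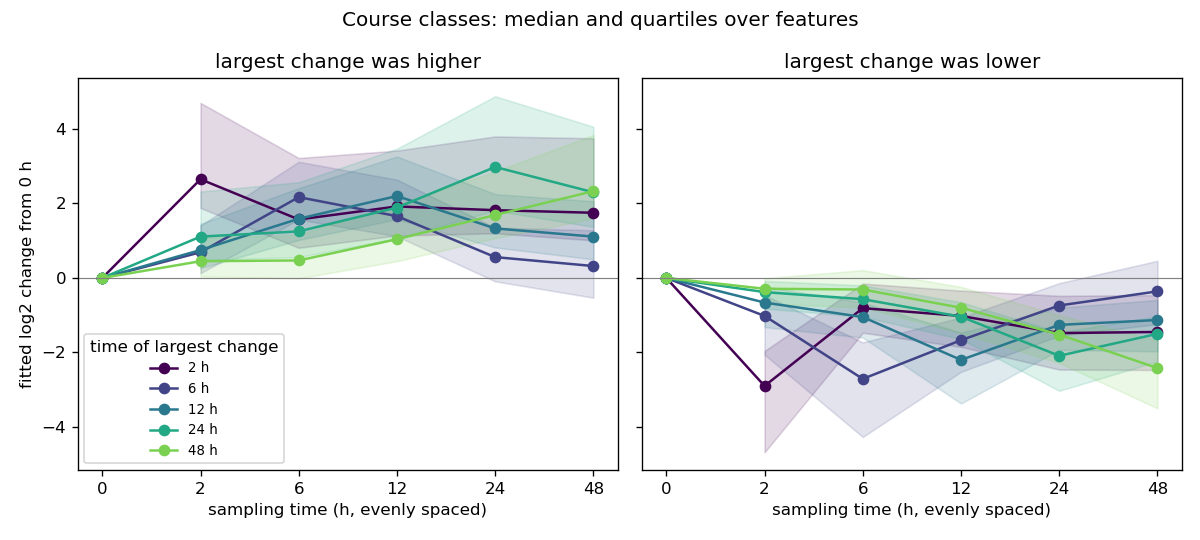
Median fitted log2 change from 0 h for features grouped by the time and direction of their largest change, with the quartiles over features as shaded bands and sampling times evenly spaced. Features with the largest rise at 6 h were at 2.17 then and 0.32 at 48 h, while those with the largest rise at 48 h were at 0.47 at 6 h.

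Samples at 24 h and 48 h share the clock time of 0 h if the stated hours were kept, while those at 12 h do not. Against the mean of 0 h, 24 h and 48 h, 2518 features were higher at 12 h and 819 were lower. Of the 7763 features called at 12 h against 0 h, 1618 were called at neither 24 h nor 48 h, 944 of them rises and 674 falls. Because the mean includes 0 h, a large change that lasted to 48 h can also enter the 2518 and 819. They are therefore not counts of passing changes. A passing response to salt and a difference between hours of the day can both enter all these counts, and the design does not separate them.

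Abundant features held a larger mean share of the counts at 48 h than at 0 h. The 100 most abundant features of a library held 12.2% ± 0.601 (SD, n = 3) of counts at 0 h, 12.1% ± 0.324 at 2 h, 13.1% ± 0.410 at 6 h, 14.9% ± 0.460 at 12 h, 16.6% ± 1.14 at 24 h and 18.7% ± 0.282 at 48 h. The lowest 48 h library (18.4%) was above the highest 0 h library (12.9%), with an exact two-sided permutation p = 0.1, the smallest that 3 libraries against 3 allow. Features were also sorted by mean level over all 18 libraries, 48 h included, so a change can itself move a feature between classes. Among features with a mean over 100 CPM, 777 rose and 215 fell at 48 h. Between 10 and 100 CPM 2355 rose and 2414 fell, between 1 and 10 CPM 2651 rose and 3131 fell, and under 1 CPM 1605 rose and 1337 fell. The most abundant feature, TRINITY_DN24130_c0_g1_i1_7 of 729 nucleotides, singled out after its values were seen, held 0.851% ± 0.133 of counts at 0 h, 1.18% ± 0.126 at 12 h and 0.475% ± 0.102 at 48 h.

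**Figure D4:**
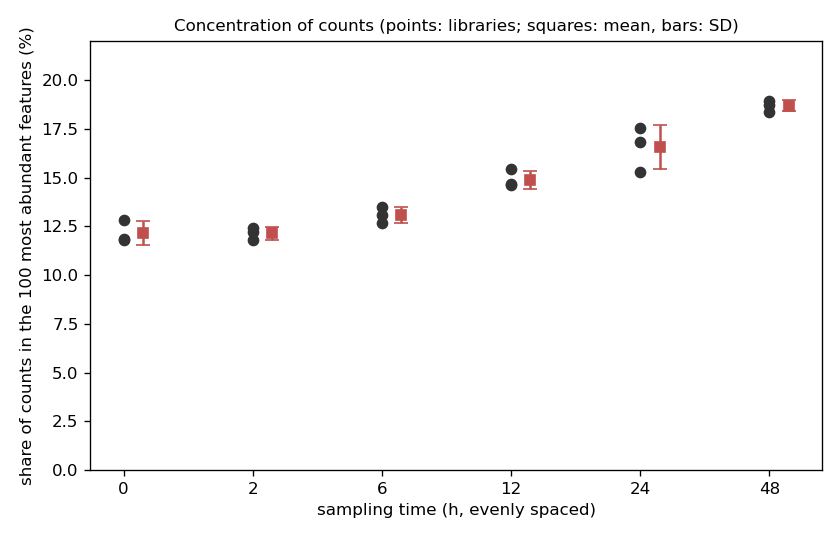
Share of each library's counts held by its 100 most abundant features, in percent, by sampling time. Points are libraries, squares are the means and bars the SD of 3 libraries; the mean went from 12.2% at 0 h to 18.7% at 48 h.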

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

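The tests of the annotation and of the feature IDs were chosen only after the patterns had been seen.

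In 166 features the calls at 6 h and at 48 h went in opposite directions. A difference between the 2 times follows from how they were selected, so a test of 48 h against 6 h on them adds nothing. The 115 that were higher at 6 h had median log2 changes of 1.74 at 6 h, 1.12 at 12 h, -0.63 at 24 h and -1.81 at 48 h. The 51 that were lower at 6 h stood at -2.16, -0.86, 0.99 and 2.30.

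The annotation columns, outside the measurements, held names that appear to belong to other sequences. Of their KEGG alignments 32.4% were over 1.1 times as long as the feature, about the share after shuffling lengths, and features with isoform number 1 were named 4.38 times as often as those with higher numbers. Both are consistent with names joined by ID from another assembly. Gaps in alignments are argued against by the 17.7% that were over 1.5 times the feature length, if the stated lengths are in amino acids. A wrong unit could itself raise this share, so the share does not argue against one. Correct names for a poorly conserved transcriptome are argued against by photosynthesis features at the 38.8th percentile of level in a leaf, a median that rests on only 9 features. No biological explanation was tested.

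The final digit of a feature ID carried a signal. Of features with at least 1 CPM, 30.9% were highest in 1 of the 2 libraries that go with their digit. For these pairs 11.3% would be if digit and library were unrelated. The pairs were picked from these same features as the 2 libraries with the largest excess, which lifts the 30.9%. The 9 pairs covered all 18 libraries. The digit may mark the libraries from which a transcript was assembled. With pairs read from features with even ID numbers, those with odd ones were compared in the same libraries. They were higher in their own libraries in 12 of 12 comparisons within a sampling time, by 0.13 to 0.38 on the log2 scale. Sampling time alone therefore does not account for the signal. Expression that differed between libraries of one time would carry over to the odd numbers, so the comparison cannot tell it from assembly. Depth does not account for the signal either, as own libraries were deeper in 6 of 12. Of calls at 48 h 10.0% were rises among features whose pair holds a 0 h library, 84.9% where it holds a 48 h library and 56% where it holds neither, and whether assembly or expression sets these shares cannot be told apart because pairs go with times. Genetic differences between wild plants stay open and untested.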

How the results depend on the processing

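The filter on length and the joint removal of the libraries labelled 0 h replicate 2 and 2 h replicate 2 were chosen after seeing the data. The cause of a moved count was not tested, except that a higher fold threshold calls fewer features by construction. The filter of 10 CPM in 3 libraries tested 17495 features and that on length 22733, where the main fit tested 45222. A lower count under these 2 filters is out of fewer features and does not mean that a smaller share was called. DESeq2 size factors moved no count of calls by over 1.5 times and the median change of all features by at most 0.04 on the log2 scale. The 4 named features kept their direction and their call in each alternative run, but the size of their log2 changes moved. At 48 h that of TRINITY_DN16846_c1_g1_i10_7 was 16.37 without 0 h replicate 3. The DESeq2 test called 2083 features at 2 h and 5318 at 6 h against 0 h, and 2796, 1230, 4074 and 1071 in the 4 steps. Only the 6 libraries compared gave 1 call at 2 h, 374 at 6 h, 83 from 2 h to 6 h and 131 from 24 h to 48 h. A log2 change of at least 2 left 1604, 4104, 6920 and 8710 calls at 6 h to 48 h and 535, 56, 794 and 84 in the steps. At least 10 CPM in 3 libraries gave 4547 at 12 h, 6320 at 24 h, 7425 at 48 h, 316 from 6 h to 12 h, 374 from 24 h to 48 h, 12923 over any time and 963 called at 12 h and at neither 24 h nor 48 h. No filter gave 71 from 6 h to 12 h and 114 from 24 h to 48 h, and limma on log2(FPKM + 1) 420 and 509. With limma the counts of calls at 12 h, at 24 h and at 48 h moved by less than 1.5 times but the balance turned. Rises and falls were 3879 and 3952, 4993 and 8521, and 4639 and 10590. The FPKM values lacked the TMM scaling, whose factors were 1.11 to 1.16 at 0 h, 1.01 to 1.04 at 12 h, 0.79 to 1.04 at 24 h and 0.74 to 0.84 at 48 h. Leaving it out lowers these times against 0 h, and how much of the turn this gives was not tested. Falls also outnumbered rises with at least 10 CPM in 3 libraries (3064 and 3256 at 24 h, 3365 and 4060 at 48 h), with at least 1000 nucleotides (3807 and 3995, 4256 and 4865) and at 48 h with only the 6 libraries compared (5857 and 6075). Features of at least 1000 nucleotides gave 7802 at 24 h and 9121 at 48 h. Leaving out one library gave 5 to 2834 calls at 2 h, 1204 to 4208 at 6 h, 5086 to 9222 at 12 h, 214 to 1337 from 2 h to 6 h, 2 to 68 from 6 h to 12 h, 609 to 2542 from 12 h to 24 h and 10 to 234 from 24 h to 48 h. Without single 0 h libraries the calls shared by 2 h were 5 to 1677 with 6 h, 5 to 2226 with 12 h, 5 to 2248 with 24 h and 5 to 2154 with 48 h. Those shared by 6 h were 1074 to 3614 with 12 h, 765 to 2840 with 24 h and 713 to 2583 with 48 h, and by 12 h with 24 h and 48 h 3701 to 6955 and 3524 to 6508. With the libraries labelled 0 h replicate 2 and 2 h replicate 2 left out together 5795 features were called at 2 h and 5358 at 6 h, the shared calls were 3103, 4053, 3903 and 3733 for 2 h and 4567, 3569 and 3274 for 6 h, and 1019 rises and 1836 falls were largest at 2 h. A largest change of at least 2 left 352 rises at 6 h, 883 rises and 584 falls at 12 h, 1231 falls at 24 h, and 2589 rises and 3355 falls at 48 h. At 10 CPM the rises and falls by time of largest change were 43 and 87, 387 and 283, 866 and 640, 1018 and 875, and 2166 and 3062. The replicate block gave 96 calls at 2 h, 599 from 2 h to 6 h and 89 from 24 h to 48 h and moved no other count by over 1.5 times; same-numbered libraries had a mean correlation of deviations of -0.03 over 45 pairs (-0.37 to 0.20), and 2 of 18 libraries correlated best with their own number, so the number does not pair them. The alternatives planned for the gene lists were not run, since the lists were not used. Depth limited changes of features near the floor of 3 counts.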

Other observations

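The exchange of labels, the thinning and the level filter were planned after the correlations of these libraries had been seen but before the results of these tests were; the correlation of the 2 libraries with each other was examined only afterwards. The libraries labelled 0 h replicate 2 and 2 h replicate 2 lay between their groups. Exchanging their labels gave 3630 calls at 2 h against 0 h, where the labels as given gave 324, as a swap would. A full swap would leave the 2 libraries as far apart as a 0 h and a 2 h library whose labels are not in doubt. Yet they correlated at 0.914 with each other, above the 0.831 to 0.859 of the 4 pairs made of replicates 1 and 3. They stood at 0.62 and 0.43 of the way from the other 0 h to the other 2 h libraries. Noise in the 2 libraries that make each end draws any library toward the middle, and no reference position was measured. These positions therefore do not speak for or against a full swap. Lower depth and low counts are argued against by the difference of mean correlations, other time minus own time. For 0 h replicate 2 it was 0.033 before and after thinning to one total, and 0.128 among features of at least 10 CPM. For 2 h replicate 2 it was 0.0162 before and after thinning, and 0.0149 at 10 CPM. The highest correlation of the 4 pairs fell from 0.859 to 0.733 at 10 CPM, so only the sign of the difference can be compared there. A partial mixture of samples, and plants that differed in their state, may each give such values and were not tested.

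Other splits of the libraries were counted for each comparison. For 2 times of 3 libraries there are 10 splits, too few for a share under 0.05. At 2 h, 2 of the 10 splits gave as many calls as the labels (324), and the highest other, the exchange above, gave 3630, which points to a structure among these 6 libraries. In the other comparisons 1 split of the 10, the real one, had as many calls. Against the real 2894 at 6 h the highest other split gave 334, with 7763 and 0 at 12 h, 12302 and 0 at 24 h, and 14485 and 1 at 48 h. In the steps the real and highest other values were 1069 and 0 from 2 h to 6 h, 109 and 17 from 6 h to 12 h, 2240 and 0 from 12 h to 24 h, and 197 and 8 from 24 h to 48 h. For any time, 1 of 30 splits, the real one with 19514, gave as many, and the highest of the 29 others drawn gave 18. A share of 1 in 30 is the smallest that 29 draws allow. It argues against random assignment to groups for that count. It does not tell sampling time from another difference that goes with the groups.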
